A study of Rattus norvegicus with 2 samples.

How the data were processed

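Total RNA of newborn rat epidermal keratinocytes was purified with a column kit, turned into biotin-labelled cDNA with a whole-transcript kit and hybridised to 1 short-oligonucleotide array per sample, per the labels' protocols. The control group had 1 array and the siTet2/3 group 1 array, and the groups were taken from the genotype in the labels. The labels call the control cells non-treated and describe transfection with or without the siRNAs; whether the control received another siRNA or transfection reagent alone is not stated there. Both cultures received vitamin C, and no array without it was used here, so the effect of vitamin C itself was not compared.

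The values are log2 signals per probe set that the authors deposited as 1 table with a column per array; the submitters' processing notes name RMA, a method of background correction, quantile normalisation and summarisation, and the Transcriptome Analysis Console, without versions or settings. The sorted values of the 2 columns differed by at most 0.151 log2 units and their medians were 4.85 (control) and 4.90 (siTet2/3), so both arrays had been brought to nearly the same distribution before deposit. Such scaling hides any difference in total RNA per cell, and folds here are relative to the bulk of the genes. Deposited values ran from 1.36 to 19.93. The upper end is higher than plain RMA of scanner signals usually gives, so a further transformation of the scale may have been applied; folds are those of the deposited scale. There were 7 genes within 0.005 of the highest value on both arrays, where a difference cannot show. The genome build and probe annotation behind the table are not given in the sources used here, and no coordinates are reported.

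The table held 24834 rows, of which 23188 were gene probes; the others were 1153 negative controls, 399 positive controls, 63 ERCC probes, 23 GC background probes and 8 spike-in probes. A platform annotation table gave 1 gene symbol for 15049 gene probes, several for 0 and none for 8139, which are unnamed here and were left out of gene counts. All 15049 entrez identifiers were found in a RefSeq gene table of assembly GRCr8, and 0 symbols needed updating. These probes covered 15037 genes; for the 10 genes with more than 1 probe the mean over probes was used. Probes of Pex19 were the furthest apart, with differences of -0.52 and 1.77. Tet1, Tet2, Tet3, Dnmt3b and Uhrf1 had no named probe, so the check of the knockdown planned for Tet2 and Tet3 was not analysed here. There were 0 columns of unknown samples.

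The difference of the log2 values, siTet2/3 minus control, was taken per gene. With 1 array per group no test was possible and no p-value is given. The background floor was the 95th percentile, over 1206 genes of olfactory, vomeronasal, taste and trace amine receptors, of the higher of the 2 values, which came to 5.04 log2 units. A gene was counted where its higher value passed the floor and its difference was at least 1.5-fold. Where 1 of the 2 values was below the floor, the fold is given as a bound, the brighter value over the floor. The 33 gene lists, among them markers of other cell types that such a culture could hold, were each summarised by the median difference of the members above the floor. Each median was placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these 2 arrays; a list was called apart in the lowest or the highest 2.5% of random lists. The expected number of lower members is the sum of the shares of 1.5-fold lower genes in the members' bins.

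Genes were named by a rule: the DNA methylation enzymes listed above together with Dnmt1, Dnmt3a and Tdg; the 12 largest increases and 12 largest decreases above the floor, leaving out placeholder and chemoreceptor symbols; and for each list up to 3 members in each direction past 1.5-fold, or, where none passed, the member with the largest difference. Other list members named beside these were chosen after their values were seen. The lists, the floor, the 1.5-fold limit, the naming rule and most alternatives were fixed before the data were examined. Settings made afterwards were the minimum of 5 members for a list median, the exclusion of Olr1 from the chemoreceptors because it encodes a lipoprotein receptor, and 4 added alternatives: a floor at the 95th percentile of the negative-control probes (8.31 log2 units) for counts and for lists, random lists matched on level, genomic length and gene density (genes within 0.5 Mb on each side, from GRCr8), and lists without the member of largest difference. The alternatives fixed beforehand were no floor, a floor 1 log2 unit higher, centring on the median difference, removal of a loess trend on level (limma loessFit, span 0.3), the brightest probe per gene, a 2-fold limit, a limit of 3 local robust SDs, means in place of medians and random lists not matched on level.

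The procedure was tested on simulated data for the comparison of siTet2/3 with control, on the 8103 genes above the floor with noise of the local spread. Of 50 genes changed 1.5-fold, 50.0% passed the 1.5-fold limit in the right direction; of 50 each changed 2-fold, 3-fold and 4-fold, 90.0%, 96.0% and 100.0% passed. Of 7903 unchanged genes, 19.1% passed the limit, since the noise was set to the whole spread seen between the arrays. Of 100 simulated lists of 30 genes, 7.0% fell outside the percentile range without a shift and 91.0% with a shift of -0.3 log2 units. Noise was drawn for each gene separately, so lists whose genes vary together were not simulated. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.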

Results

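Gene expression was measured on whole-transcript oligonucleotide arrays in cultured epidermal keratinocytes of newborn rats, the cells that build the outer layer of the skin. The cells were grown in medium with serum and hydrocortisone. 1 array held the control and 1 array held cells transfected with siRNAs against Tet2 and Tet3 (siTet2/3), at 1 µM each. TET proteins are enzymes that oxidise methylated cytosine in DNA, and vitamin C promotes their activity. Both cultures received vitamin C for 12 h, starting 24 h after transfection, so the arrays compare control and siTet2/3 cells in the presence of vitamin C. Each group had 1 array, so no difference below has a replicate check, and "higher" and "lower" describe these 2 arrays only. Their number limits the precision of every value. The log2 signals of the 2 arrays had a Pearson correlation of 0.989 across 23188 gene probes, which are not independent replicates. A total of 8103 named genes lay above the background floor of 5.04 log2 units on at least 1 array.

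The comparison asked which genes differed between vitamin C-treated keratinocytes with and without siRNAs against Tet2 and Tet3. The size of the knockdown itself was not analysed here, because none of the 3 Tet genes had a named probe. Of the other DNA methylation enzymes, the maintenance methyltransferase Dnmt1 read 10.40 log2 units on the control array and 10.43 on the siTet2/3 array. The de novo methyltransferase Dnmt3a read 5.08 and 5.17, close to the floor. Tdg, a glycosylase that removes oxidised methylcytosine, read 11.54 and 11.24.

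Among genes above the floor that carry a gene name rather than a placeholder, Crip2, which encodes a LIM-domain protein, differed most and was 9.09-fold lower on the siTet2/3 array (9.85 against 6.67 log2 units). Next among genes lower on the siTet2/3 array were the serine protease gene Prss22 (5.13-fold), the effector caspase gene Casp6 (4.37-fold), Csf3, which encodes granulocyte colony-stimulating factor (4.13-fold), and the natriuretic peptide gene Nppb (3.89-fold). The mitochondrial carrier gene Slc25a39 was 3.48-fold lower, the ciliary transport gene Ift56 3.45-fold lower and the interleukin-23 subunit gene Il23a 3.34-fold lower. In the other direction, Krt15, a keratin of basal keratinocytes and of the hair follicle bulge, was 5.59-fold higher on the siTet2/3 array (8.78 against 11.26 log2 units). Igfbp5, which encodes a binding protein of insulin-like growth factors, was 4.28-fold higher, from 11.90 log2 units on the control array. Hpgd, which encodes a prostaglandin-degrading dehydrogenase, was 3.72-fold higher, Amph, which encodes amphiphysin, 3.69-fold and Asb12 3.60-fold. Of these genes, Prss22, Casp6, Ift56, Il23a, Hpgd and Asb12 lay on both arrays below 8.31 log2 units, the alternative floor from negative-control probes.

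The remaining genes named by this rule lay below the floor on 1 array, so their folds are lower bounds. This was the case for 7 of the 12 largest increases. Fli1, a transcription factor gene, was at least 1.89-fold higher, the hyaluronan synthase gene Has3 at least 1.30-fold, the imprinted gene Ndn at least 1.29-fold and Havcr2 at least 1.27-fold. The bounds for Mgat4d, Itpkb and Csn3 were 1.20-fold, 1.09-fold and 1.06-fold. Of the 12 largest decreases, 4 were below the floor on the siTet2/3 array. Dph2 was at least 1.21-fold lower, the interleukin-36 receptor antagonist gene Il36rn at least 1.18-fold and Dok6 at least 1.11-fold, while Abcg5 stood at the floor on the control array, so its bound was 1.00-fold.

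Of the 8103 genes above the floor, 699 were at least 1.5-fold higher on the siTet2/3 array and 1070 at least 1.5-fold lower, or 21.8% in all. After centring on the median difference the counts were 845 and 899, and after removal of a trend on level 833 and 900, so the excess of lower genes depended on the scaling. At 2-fold the counts were 147 higher and 247 lower, and 78 and 186 among the 7504 genes above the floor on both arrays. With values under the floor raised to it, 564 genes were 1.5-fold higher and 954 lower. All counts, those of the gene lists included, are of differences as measured, so a gene with 1 value below the floor can be counted although its bound is under 1.5-fold. Among 1206 chemoreceptor genes, which were taken as a gauge of background, 207 were 1.5-fold higher and 141 lower, or 28.9%. The differences narrowed with signal, from a robust SD of 0.42 log2 units at levels of 7.85 to 8.20 to 0.27 above 14.24. In the dimmest of 20 equal bins of the genes above the floor it was 0.91. Genes were chosen by their higher value and binned by their mean. Those with a mean below the floor therefore had to differ to be counted, and 0.91 does not measure noise there. Genes at the top of the scale, such as Actb, Eef1a1 and Hspa8, read 19.93 on both arrays, where the deposited values end.

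**Figure D1:**
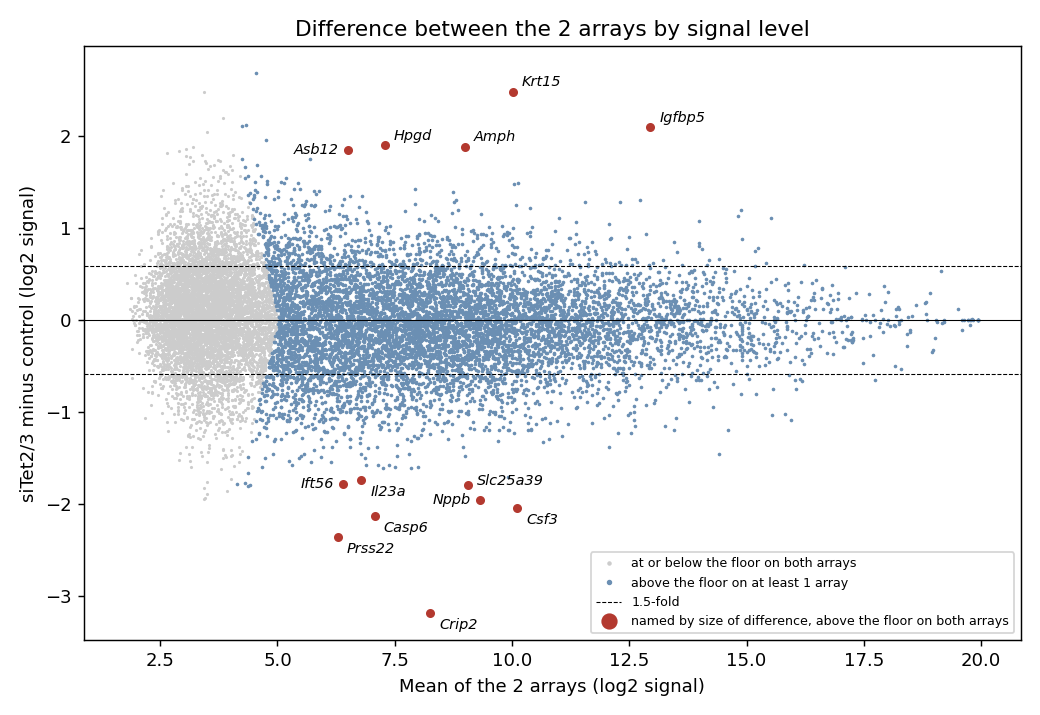
Difference between the 2 arrays (siTet2/3 minus control, log2 signal) against the mean of the 2 arrays (log2 signal), 1 point per named gene, with the 1.5-fold lines dashed. Grey points are genes at or below the floor on both arrays, blue points those above it on at least 1 array, and red points the genes named by size of difference that were above the floor on both arrays; Crip2 lies lowest at -3.18 and Krt15 stands at 2.48.

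Inflammatory signalling genes were lower on the siTet2/3 array as a group. Of 30 NF-kB and cytokine genes above the floor, 13 were at least 1.5-fold lower, 3 were at least 1.5-fold higher and 14 were neither, where genes of the same level would give 3.75 lower; with values raised to the floor 12 were lower. Besides Csf3 and Il23a, the growth factor gene Csf2 was 2.74-fold lower, the neutrophil chemokine gene Cxcl1 2.05-fold lower, the cytokine gene Il24 2.03-fold lower (16.33 against 15.31 log2 units) and Il1a 1.91-fold lower. Nfkb1, which encodes an NF-kB subunit, was 1.70-fold lower. The chemokine gene Ccl20 was 2.29-fold higher, Il36g 1.59-fold and the siderophore-binding lipocalin gene Lcn2 1.52-fold. The list median was -0.49, at percentile 0.0: none of 10000 random lists matched on level had a lower median. Over all 41 members on the array, with no floor set, the median was -0.30 at percentile 0.06. The 4 immune cell markers above the floor were also all lower, by a mean of 0.23 log2 units.

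Hypoxia and HIF target genes, several of which encode glycolytic enzymes, were also lower as a group. Of 31 members, 8 were at least 1.5-fold lower, 0 were higher and 23 were neither. Pfkfb3, a regulator of glycolysis, was 2.82-fold lower, the angiogenic factor gene Vegfa 2.05-fold lower (16.06 against 15.02 log2 units) and the transcriptional repressor gene Bhlhe40 1.94-fold lower. The glycolytic genes Ldha and Pgk1 differed by -0.04 and 0.04 log2 units, from 19.17 and 18.17 on the control array. The list median of -0.32 lay at percentile 0.01.

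Genes of keratinocyte activation and wound response included 7 of 17 that were at least 1.5-fold lower, where genes of the same level would give 1.88, and 0 that were higher. The urokinase receptor gene Plaur was 2.30-fold lower, the EGF receptor ligand genes Tgfa, Areg and Hbegf 2.22-fold, 2.09-fold and 1.90-fold lower, and the urokinase gene Plau 2.13-fold lower. The keratin gene Krt17 read 18.19 and 18.12 log2 units. The list median of -0.25 lay at percentile 5.06, inside the range set for calling a list apart, which left out the lowest and the highest 2.5% of random lists; with the mean in place of the median (-0.41) it lay outside, at percentile 0.03. It lay further inside with matching on gene length and density as well (percentile 11.5) or without the member of largest difference (14.4, median -0.18).

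**Figure D2:**
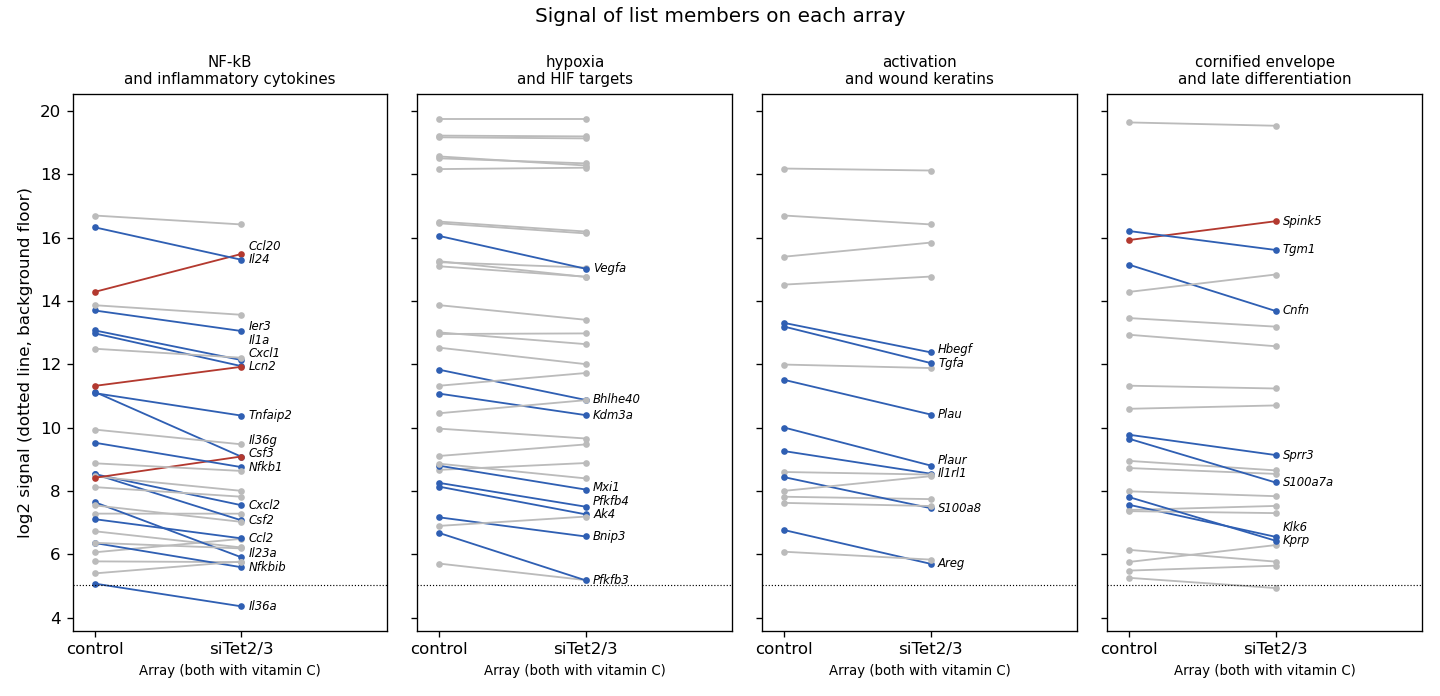
Signal (log2) of each list member above the floor on the control and the siTet2/3 array, 1 line per gene, for 4 gene lists; the dotted line is the floor of 5.04. Blue lines are genes at least 1.5-fold lower on the siTet2/3 array (13, 8, 7 and 6 genes from left to right), red lines genes at least 1.5-fold higher (3, 0, 0 and 1), and grey lines the rest.

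Late differentiation genes were mixed. Of 22 cornified envelope genes, 6 were at least 1.5-fold lower and 1 was higher, but 5 and 3 after centring on the median difference and 4 and 3 after removal of the trend on level. Cnfn, which encodes cornifelin, was 2.75-fold lower (15.15 against 13.69 log2 units), S100a7a and the keratinocyte proline-rich protein gene Kprp 2.60-fold each, and the envelope cross-linking transglutaminase gene Tgm1 1.51-fold, though not past 1.5-fold after centring or removal of the trend. Spink5, an inhibitor of the proteases that shed corneocytes, was 1.51-fold higher. The envelope precursor gene Ivl differed by -0.15 log2 units. The list median of -0.23 lay at percentile 3.84, inside the range. It lay outside with the mean (-0.30, percentile 0.43) and with a floor from negative-control probes (percentile 2.10), and further inside with matching on gene length and density as well (10.2) or without the member of largest difference (10.2, median -0.18). Spinous and early differentiation genes had 3 of 24 members at least 1.5-fold lower, the desmosomal plakophilin gene Pkp3 (1.89-fold), the tight junction gene Cldn4 (1.75-fold) and Ptgs1 (1.62-fold), and 0 higher. The spinous keratin gene Krt1 differed by -0.45 log2 units, while the junctional genes Jup, Dsg3 and Perp differed by at most 0.07. The spinous list median, also -0.23, lay at percentile 1.06, outside the range. It lay inside under 4 of the 10 alternatives tried, with a median of -0.12 where no floor was set. Those 10 included centring, removal of the trend and the brightest probe, which could hardly move a percentile.

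Basal layer genes went both ways. Of 23 members, Krt15 and the matrix glycoprotein gene Thbs1 (2.18-fold) were at least 1.5-fold higher on the siTet2/3 array, and Sostdc1, below the floor on the control array, was at least 1.28-fold higher. The 3 lower ones were Bnc1 (1.90-fold), Ccn2 (1.67-fold) and Igf1r (1.61-fold). Krt14, the main basal keratin on the array, read 18.54 and 18.70 log2 units, and Tp63, the master transcription factor gene of stratified epithelium, 13.15 and 12.75. The median was -0.06 at percentile 38.9. For barrier lipid genes the median was -0.14 at percentile 17.6 (-0.22 at percentile 8.39 with a floor from negative-control probes), with 4 of 28 lower, among them Ppard (2.30-fold), the ceramide synthase gene Cers2 (1.86-fold) and the ceramidase gene Asah1 (1.74-fold). Elovl3 was higher in that list, at least 1.29-fold. Genes of the same level as the barrier lipid list would give 3.41 lower.

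Of 36 keratinocyte transcription factor genes, 9 were at least 1.5-fold lower and 4 higher as measured, or 7 and 3 with values raised to the floor, with a median of -0.06 at percentile 48.2. The AP-1 genes Jun and Fosl1 were 2.43-fold and 1.95-fold lower, Tfap2c was 2.19-fold lower and Ovol1 at least 1.86-fold lower. Maf, which acts in late keratinocyte differentiation, was 2.63-fold higher, Arnt2 1.71-fold and Klf5 1.58-fold. In the Notch pathway the Notch inhibitor gene Numb was 2.25-fold lower, while Hey1 and Notch3 were higher, at least 1.19-fold and 1.09-fold. The median of the 17 Notch genes was 0.15 at percentile 90.3.

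The list of DNA methylation and demethylation genes, without Tet1, Tet2 and Tet3, had a higher median on the siTet2/3 array than matched genes. Of 19 members above the floor, 4 were at least 1.5-fold higher and 0 lower: the growth arrest gene Gadd45g (1.75-fold), the chromatin remodeller gene Hells (1.62-fold), the isocitrate dehydrogenase gene Idh1 (1.52-fold) and the O-GlcNAc transferase gene Ogt (1.51-fold). Genes of the same level would give 1.66 higher. The rise was not shared by all members: Dnmt1 and Dnmt3a differed by 0.03 and 0.09 log2 units, and 5 members were below 0, among them Tdg (-0.31) and Neil1 (-0.50). The list median of 0.27 lay at percentile 99.5, and with a floor from negative-control probes it was 0.43 over 11 members. Without the member of largest difference the median was 0.20, at percentile 97.54, barely outside the range. Genes for vitamin C uptake and ascorbate-dependent hydroxylases had 6 of 30 members at least 1.5-fold lower and 0 higher (5 and 1 after centring or removal of the trend on level), with a median of -0.07 at percentile 44.5; it was -0.20 at percentile 9.60 with a floor from negative-control probes, and 0.00 at percentile 72.7 without the member of largest difference. The lower ones were histone demethylase genes with the exception of Hif1an, which fell short of 1.5-fold after centring or removal of the trend, led by Phf8 (2.33-fold), Kdm6b (1.81-fold) and Kdm4b (1.77-fold).

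Among germline genes kept silent by methylation in somatic tissue, only 6 of 33 on the array passed the floor. Sycp3, a meiotic chromosome axis gene, was 1.71-fold higher, and Dmc1 and Smc1b at least 1.33-fold and 1.01-fold higher. Their median was 0.56 at percentile 95.7, 0.23 over all 33 with no floor set, and 0.17 with values under the floor raised to it; the median lay outside the range, at percentile 98.7, with matching on gene length and density as well, and inside, at 80.8, without the member of largest difference. Among 10 imprinted genes, Th (2.29-fold), Igf2r (1.86-fold) and Ndn (a bound of 1.29-fold) were higher and Impact (1.87-fold) lower; the median was 0.25 at percentile 96.7, and -0.11 over all 25 members on the array with no floor set, while the mean of 0.32 lay outside the range, at percentile 99.2. With matching on length and density the imprinted median lay at percentile 90.4. Canonical histone genes had a median of -0.13 at percentile 29.4 (0.00 with no floor set, -0.26 with a floor from negative-control probes, and a mean of -0.03), with 1 of 15 lower, H2ac21 (1.53-fold), and after centring or removal of the trend 0 lower and 1 higher.

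Proliferation genes did not stand apart as groups. Of 35 genes of the G2/M phase, 6 were at least 1.5-fold lower and 0 higher, but only 3 were lower after centring or removal of the trend on level. The 6 included the kinetochore gene Nuf2 (2.48-fold), the spindle gene Nusap1 (2.17-fold) and Hmmr (1.56-fold, not past 1.5-fold after removal of the trend), while Mki67 read 12.65 and 12.81 log2 units. The median was -0.11 at percentile 25.4, and 0.01 with a floor from negative-control probes. Genes of the same level would give 3.94 lower. Of 41 S-phase genes, 3 were lower and 1, Hells, was higher (3 and 2 after centring or removal of the trend), with a median of -0.10 at percentile 28.1 (-0.03 with a floor from negative-control probes). The lower ones were the DNA polymerase subunit gene Pold3 (2.15-fold), Rfc4 (1.85-fold) and Gins1 (1.84-fold). Genes of the same level would give 5.00 lower.

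Stress response lists differed little from matched genes, apart from the unfolded protein and integrated stress response. There 7 of 36 genes were at least 1.5-fold lower as measured, or 6 with values raised to the floor, and Vldlr was higher with a bound of 1.46-fold. Trib3 was 1.75-fold lower, Stc2 1.73-fold and Cebpb at least 1.23-fold, while the chaperone gene Hspa5 differed by -0.24 log2 units. The median of -0.20 lay at percentile 2.23. It lay inside the range under 7 of the 10 alternatives tried, and outside only with centring, removal of the trend or the brightest probe. Those settings could hardly move a percentile, so this list stood apart only narrowly. NRF2 and oxidative stress genes had a median of -0.17 at percentile 7.40 (-0.06 at percentile 27.2 with no floor set), with the thioredoxin reductase gene Txnrd1 (2.29-fold), Abcc3 (1.76-fold) and Prdx6 (1.74-fold) among 5 of 30 that were lower, and Taldo1 1.59-fold higher. Of 30 p53 targets, 5 were lower, led by the apoptosis gene Bax (1.95-fold), Ccng2 (1.81-fold) and Fas (1.62-fold), and 2 were higher, Tp53inp1 (1.64-fold) and Polh (1.63-fold), but 3 lower and 3 higher after centring or removal of the trend on level; the median was 0.04 at percentile 83.2, and -0.06 with a floor from negative-control probes. Genes of the same level as the p53 targets would give 3.73 lower. Of 17 heat shock genes, Hspa4l was 3.02-fold lower, Cryab 1.56-fold lower (but not after removal of the trend) and Dnajb4 1.51-fold higher, with a median of -0.07 at percentile 34.5.

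Of 22 interferon response genes, Irf9 was lower by at least 1.41-fold, Rsad2 was 1.69-fold lower and Dtx3l 1.52-fold higher (2 lower and 2 higher after centring, 2 and 3 after removal of the trend), with a median of -0.12 at percentile 29.9. Cholesterol and lipid synthesis genes had a median of -0.03 at percentile 59.4 (0.02 after centring, 0.03 after removal of the trend on level). In that list Acaca (1.89-fold), Idi1 (1.63-fold) and Scd (1.53-fold) were higher and Lss (1.61-fold) and Dhcr7 (1.52-fold) lower, the last not after centring or removal of the trend. Among 19 TGF-beta targets the matrix genes Tgfbi (1.98-fold) and Fn1 (1.74-fold) and the repressor gene Id2 (1.80-fold) were higher and Ccn2 and Pmepa1 (1.65-fold) lower (5 higher and 2 lower after centring), with a median of -0.08 at percentile 35.2. The 4 fibroblast markers above the floor were all higher too, by a mean of 0.39 log2 units. Wnt genes had a median of 0.14 at percentile 86.0, and only Wnt5a passed 1.5-fold as measured, with a bound of 1.36-fold lower (1 lower and 1 higher after removal of the trend).

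Markers of other cell types were mostly at background. Only 4 of 28 immune cell markers on the array, 4 of 22 fibroblast markers, 2 of 11 melanocyte markers and 2 of 20 endothelial and mural markers lay above the floor, too few for a list median. The fibroblast marker Sparc, also made by other cells, was 1.69-fold higher (14.80 against 15.55 log2 units), the melanosome gene Rab38 read 6.52 and 6.88, the macrophage marker Cd68 5.52 and 5.24, and the endothelial gene Tek 9.66 and 9.25. Of 8 hair follicle, sebaceous and simple epithelial markers above the floor, Krt19 was 1.62-fold and Scd 1.53-fold higher, with a median of 0.14 at percentile 80.4 (0.04 without the member of largest difference). Of 6 neuronal and glial markers, the myelin gene Pmp22 was 3.27-fold lower and Sox2 at least 1.59-fold lower, with a median of -0.27 at percentile 15.95 and a mean of -0.48 outside the range, at percentile 2.02; without Pmp22 the median lay at percentile 29.3. The Y-linked genes Ddx3y and Eif2s3y were above the floor on both arrays, at 6.14 and 6.54 and at 7.60 and 7.44 log2 units. Housekeeping genes had a median of -0.05 at percentile 37.9 (0.01 after centring on the median difference of all genes above the floor), with 1 of 27, Gusb, past 1.5-fold (1.58-fold lower). No mitochondrially encoded transcript had a named probe.

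Of the 27 lists with at least 5 members above the floor, 4 had medians below percentile 2.5 of matched random lists (NF-kB and cytokines, hypoxia, spinous layer, unfolded protein response) and 1 above the upper 2.5% bound (DNA methylation machinery). Random lists would give 1.35 of 27 outside that range. Genes of a real list may vary together between any 2 cultures, and some lists share members. The 5 lists against 1.35 therefore do not measure an excess. These percentiles describe 2 arrays and not the spread between cultures.

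**Figure D3:**
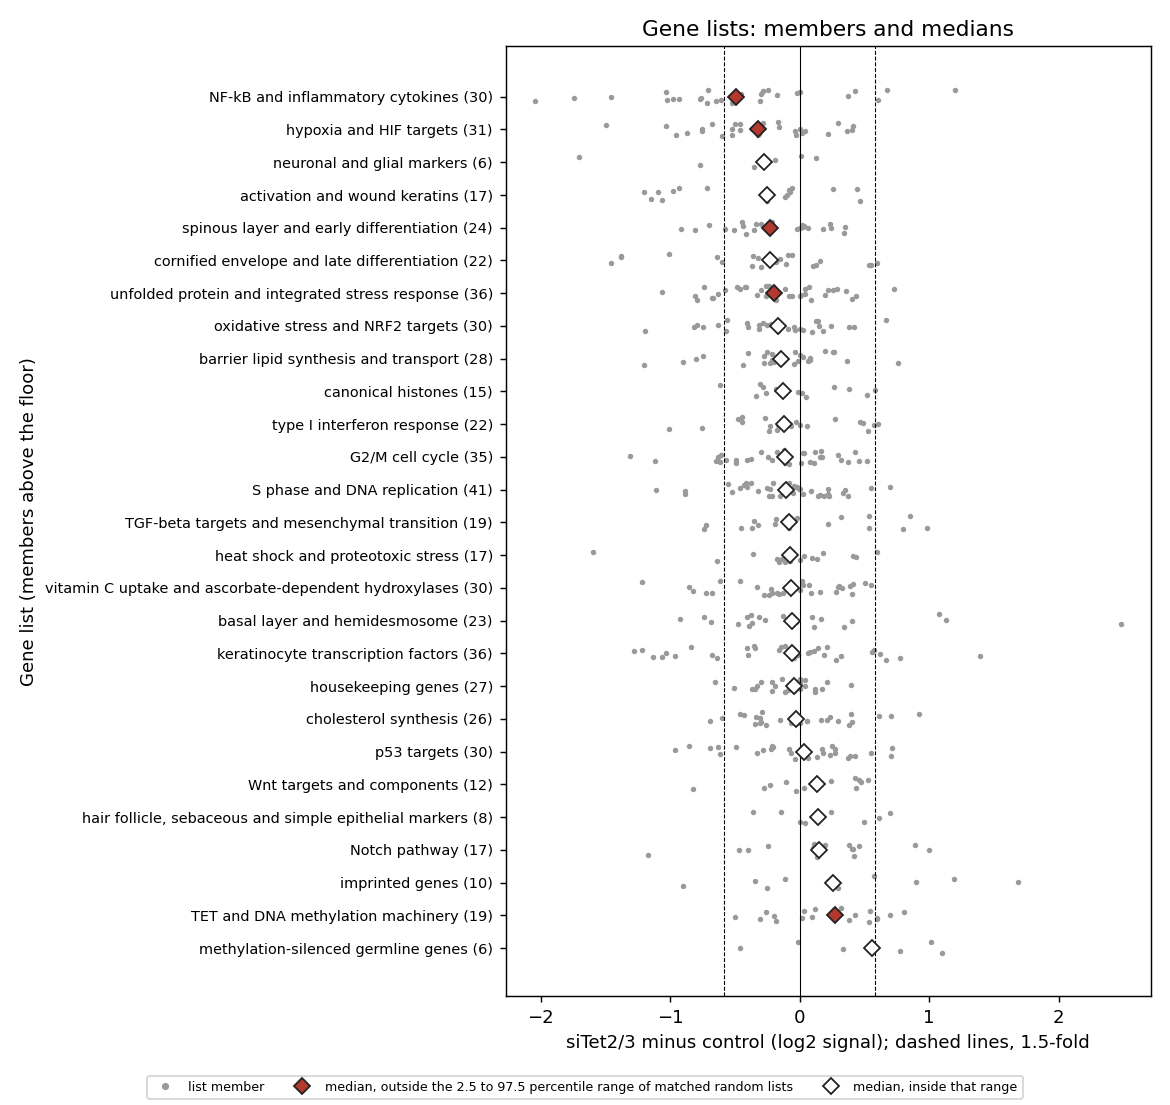
Difference (siTet2/3 minus control, log2 signal) of each gene above the floor (grey points) in the 27 lists, with the list median as a diamond and the 1.5-fold lines dashed; numbers in brackets give the members above the floor. Red diamonds are the 5 lists in the outer 2.5% of matched random lists on either side, from -0.49 for NF-kB and cytokine genes to 0.27 for the DNA methylation machinery.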

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

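The tests of gene length and density, of immune cells and of a difference between the cultures were chosen only after the result was seen; that of the level trend was set before. Control probes, which served only for an alternative floor, showed 12 increases on the siTet2/3 array larger than the 3.18 log2 units between the arrays for Crip2, the most different named gene. For 10 negative-control probes the increases were 3.22, 3.28, 3.40, 3.42, 3.51, 3.61, 4.06, 5.02, 10.58 and 10.58 log2 units, and for 2 positive-control probes 4.07 and 6.09. Another 11 control probes were lower by as much, and the robust SD of negative-control differences was 0.92. The largest pair read 6.72 and 5.60 on the control array and 17.31 and 16.19 on the siTet2/3 array. The largest increase among gene probes, named or not, was 2.68. The source of the brightness and of the equal size of the pair stays open, and neither a technical nor a biological explanation was tested.

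The lower signal of inflammatory cytokine genes on the siTet2/3 array was weighed against technical causes. A level-dependent trend between the arrays accounted for little of it: the list median was -0.49 before and -0.42 after removal of the loess trend. The percentile, 0.0 both times, could hardly move, because the random lists were already matched on level. Short genes in gene-dense regions did read lower on the siTet2/3 array, but random lists matched on level, length and density also left the list at percentile 0.0. Immune cells in the control culture are argued against by their markers, of which 14.3% of the 28 on the array (4 genes) were above the floor there, while abundant transcripts of such cells lay below it, with Ptprc at 2.78, Tyrobp at 2.75 and Lyz2 at 3.69 log2 units. The 4 markers above the floor were all lower on the siTet2/3 array, by less than the cytokine list (a mean of -0.23). With 1 array per group, a difference between the 2 cultures apart from the siRNA, such as density or handling, cannot be told apart from an effect of Tet2 and Tet3, which stays a hypothesis. The same holds for effects of transfection, or of the siRNAs on anything but Tet2 and Tet3. What the control received is not stated, and the knockdown was not checked.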

How the results depend on the processing

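The alternatives using the negative-control floor, length and density matching and lists without their most different member were chosen after the data were seen. Against 699 genes higher and 1070 lower, the counts were 1684 and 1690 without a floor, 248 and 453 with the negative-control floor, 147 and 247 at 2-fold, and 26 and 38 beyond 3 local robust SDs; fewer or more genes, or a stricter limit, make these by construction. A floor 1 log2 unit higher gave 497 and 868, centring 845 and 899, loess 833 and 900, and the brightest probe 698 and 1070. The lower genes' share of those past 1.5-fold was 60.5%, but 51.5% after centring, 51.9% after loess and 50.1% without a floor. The NF-kB, hypoxia and DNA methylation lists stayed outside the percentile range under all 10 alternatives. For the DNA methylation list this was narrow: without the member of largest difference its median was 0.20, at percentile 97.54, barely past the upper bound. Not every alternative could have moved a list, however. Centring shifts a list and its random lists alike, so it changes no percentile. The brightest probe concerned only 10 genes, and for loess the random lists were already matched on level. The spinous list moved inside under 4 alternatives and the unfolded protein list under 7, all but centring, loess and the brightest probe. In the other direction, 5 lists lay outside only under an alternative: with means, activation and wound genes (percentile 0.03), cornified envelope (0.43), imprinted (99.2) and neuronal and glial genes (2.02); cornified envelope genes with the negative-control floor (2.10); and germline genes with random lists not matched on level (99.8) or matched on length and density (98.7). Under the other alternatives these lists lay inside the range, in part close to its bounds: from 3.94 to 14.4 for activation and wound, 3.74 to 10.2 for cornified envelope, 12.9 to 97.0 for imprinted, 7.59 to 29.3 for neuronal and 80.8 to 96.7 for germline genes. Without a floor the median of the NF-kB list was -0.30 and of the spinous list -0.12, and with the negative-control floor that of the DNA methylation list was 0.43; the cause was not tested. For the other lists 202 of 213 alternative values moved by less than the error of the median and 11 by more. These counts do not measure stability, because a part of the values could not move. Changing how random lists are matched leaves the list median as it was, and centring shifts all medians by the same small amount. The mean had the opposite sign to the median for basal (0.02), p53 (-0.03) and TGF-beta genes (0.03), and cholesterol genes changed sign after centring (0.02) and loess (0.03), as did housekeeping genes after centring (0.01). The negative-control floor turned the sign of G2/M (0.01), p53 (-0.06) and cholesterol genes (0.03), and no floor that of histone (0.00) and imprinted genes (-0.11). The 118 genes named by rule kept their direction in all 354 values under centring, loess and the brightest probe and moved by less than the local spread. For centring and the brightest probe this was close to fixed in advance. Each named gene had 1 probe, and centring took the same median difference of -0.05 from all of them. Still, 4 of the 112 past 1.5-fold fell short of it: Dhcr7 (-0.55 and -0.53) and H2ac21 (-0.56 and -0.55) under centring and loess, and Cryab (-0.57) and Hmmr (-0.58) under loess. Of 133 list members past 1.5-fold, 15 fell short of it under centring or loess, Tgm1 (-0.54 and -0.56), Hif1an (-0.56 and -0.55) and 4 of the 6 lower G2/M genes (Aurka, Ccna2, Hmmr and Kif2c) among them. Alternatives for Tet2 and Tet3 were not run, as neither had a named probe, and using all members on the array is the same setting as no floor. No paired analysis was possible because each group had 1 array. In the dimmest bin 54.2% of genes passed 1.5-fold, against 7.39% in the brightest. The choice of genes by their higher value raises the first share, so it does not measure noise near the floor. Of the chemoreceptor genes, taken at any level, 28.9% passed, so small differences of dim genes carry little weight.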

Other observations

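The tests of basal cells and hair follicle cells were chosen only after Krt15 was seen, and the transporter genes named here were chosen after their values were seen; matching on length and density was added after the data were seen, and the lists for ERK and FOXO were written before their medians were seen. The copper importer gene Slc31a1 read 11.43 log2 units on the control array and 10.13 on the siTet2/3 array. The amino acid transporter genes Slc6a14 and Slc1a5 read 16.48 and 15.40 and 7.80 and 6.69, while the zinc transporter gene Slc39a8 was higher, at 12.08 and 13.38.

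Across the genome, the difference between the arrays followed gene density and length. Among 8090 genes above the floor with a position, the median difference went from 0.03 in the lowest to -0.13 in the highest of 5 equal groups by the number of neighbouring genes. By genomic length it went from -0.11 in the shortest to 0.05 in the longest of 5 such groups, with standard errors of the medians of at most 0.02. Among 3560 unnamed gene probes above the floor, 391 were 1.5-fold higher and 444 lower.

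Several early-response genes such as Jun, Fosl1 and Areg were among the lower ones, and lower ERK-driven transcription may account for this as a hypothesis. A list of ERK feedback and early-response genes, written without these named genes, had a median of -0.40 over 19 members, at percentile 0.235 of matched random lists. Of the members, 16 were below 0, 5 were at least 1.5-fold lower, where genes of the same level would give 2.17, and 0 were higher. The list was read on the same 2 arrays that prompted it, so it is no independent support. Dusp6, a phosphatase induced by ERK, read 12.50 and 11.44 log2 units, Hmga1 9.82 and 8.90 and Egr1 11.36 and 10.65. The percentile was 0.26 with matching on length and density and 0.34 after loess. No protein or phosphorylation was measured, and 1 array per group leaves differences of culture and transfection open.

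Sesn3 and Pik3r3 were among the higher genes (2.81-fold and 2.79-fold), which raised higher FOXO-driven transcription as a hypothesis. A FOXO target list without them showed no general rise. Its 23 members had a median of -0.02 (standard error 0.13) at percentile 63.2. Of the members, 13 were below 0, 5 were at least 1.5-fold lower and 2 at least 1.5-fold higher. Whether FOXO-driven transcription differed cannot be told from these values, because 1 array per group gives no spread between cultures. A rise limited to a few targets cannot be excluded.

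The higher Krt15 was set against a larger share of basal cells or of hair follicle cells in the siTet2/3 culture. The other 22 basal list members had a median of -0.10 (standard error 0.11) at percentile 27.2, against 2.48 for Krt15. These values show no general rise of basal genes. They cannot exclude a larger share of cells with high Krt15, since other basal genes need not follow cell share by a like amount. Hair follicle cells stay open: only 33.3% of their 24 markers on the array (8 genes) were above the floor, of which 5 were higher and 2 lower on the siTet2/3 array. A difference in Krt15 within the same cells may remain and was not tested, because each group had 1 array.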
